A study of Mus musculus with 4 samples.

How the data were processed

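RNA was measured in 4 xenograft tumors grown from MDA-MB-231 cells, a human triple-negative breast cancer line, in the mammary fat pads of female athymic nude mice. 2 tumors came from cells carrying a control short hairpin RNA (shRNA) and 2 from cells carrying an shRNA against DHHC3, the protein encoded by ZDHHC3. Per the labels' protocols, total RNA was converted to cDNA, amplified by in vitro transcription into biotin-labelled cRNA and hybridised, 1 sample per array. The labels give the organism of the samples as mouse, the host, but the probe sets of the table are annotated as those of a human expression array. The values therefore concern human transcripts, and how much mouse host RNA bound to the same probes was not measured.

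The authors deposited 1 table of processed probe set intensity on a linear scale, with 137 probe sets and 1 column for each of the 4 arrays. No value was 0 or negative. The summarisation, background correction, scaling between arrays, detection calls and the rule by which these probe sets were chosen are not given in the sources used here. The other probe sets of the array were not analysed here. In every one of the 137 probe sets, both arrays of one group lay outside the range of the other, and the nearest arrays of the 2 groups differed by at least 1.56-fold. The table thus holds probe sets that already separate the groups, and no test run within it can tell how many genes of the whole array differed.

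Gene names came from the platform annotation of the probe sets. 101 probe sets had 1 gene symbol, for 99 genes, 7 had several and 29 had none listed. Probe sets with several symbols were counted but no gene was named from them. Where a gene had more than 1 probe set, its brightest one stood for it in the rule for named genes and in 1 alternative. The main test and its counts used all 137 probe sets. No human genome was used here, so no genomic positions are given.

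Intensities were turned into log2 values without a pseudocount and without further normalization. The DHHC3-ablated arrays were compared with the control arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, all 4 arrays, no covariates), and p-values were adjusted with the Benjamini-Hochberg method over the 137 probe sets, with a threshold of 0.05. A gene was said to have risen or fallen when its adjusted p was under that threshold. Fold changes are ratios of geometric means. Fisher's exact tests used scipy 1.17.1 in Python 3.11.15, and figures were drawn with matplotlib 3.10.9. With 2 arrays per group, an exact two-sided permutation test of a single gene cannot go below p = 0.333. The number of arrays limits the precision. Nothing in the labels says whether the 2 tumors of a group came from separate animals, so the p-values measure the spread between these samples only.

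The procedure was tested on simulated data. In the first simulation the variances were drawn from the limma fit to the 137 listed probe sets. Its recovery therefore holds for that spread and not for the whole array. With 2000 simulated probe sets, of which 200 were changed, limma recovered 76.5% of 1.5-fold changes, 96% of 2-fold changes and 97.5% of 3-fold changes. The share of false calls was 4.38%, 7.25% and 3.47% in the same order. A second simulation addressed the selection. From 20000 unchanged probe sets, those that separated the groups by 1.56-fold or more were picked and tested alone. At an SD of 0.101 on the log2 scale, the value fitted to the deposited list, 18 were picked and limma called 17 of them, against 0 when all 20000 were tested together. At assumed SDs of 0.2, 0.3 and 0.4, it called 157 of 159, 414 of 426 and 781 of 819 picked probe sets, against 1, 0 and 0 when all were tested together. The spread of the whole array is unknown, so these counts do not estimate how many listed probe sets are unchanged; they show that most picked unchanged probe sets pass. The adjusted p-values therefore describe how far apart the groups lie within this list and are not independent evidence that a listed gene differs.

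These choices were made before the data were examined: the test, the alternatives, the gene lists and the rule for the genes named. The rule took ZDHHC3 and TXNIP, then the 12 highest and the 12 lowest fold changes among probe sets with 1 gene name that passed the test and whose groups did not overlap, then up to 4 members of each gene list. 26 lists were fixed. The lists of processes were antioxidant and NRF2 targets, the thioredoxin system, senescence and its secreted factors, proliferation, the unfolded protein response, hypoxia and glycolysis, the interferon response, inflammatory cytokines and chemokines, DHHC acyltransferases and thioesterases, integrins with tetraspanins and matrix, apoptosis and p53 targets, and lipid and sterol metabolism. The lists of cell types covered macrophages, neutrophils, NK cells, dendritic cells, B cells, endothelial cells, pericytes with smooth muscle, fibroblasts, adipocytes, skeletal muscle, erythroid cells, mammary epithelium, keratinocytes and Schwann cells. A set test needed 5 measured members. No list reached that number in the table, so no set test was run.

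The alternatives were centring each array on its median, quantile normalization, leaving out the dimmest 25% of probe sets, the replicate number as a block, leaving out each array in turn, a pseudocount of 16, eBayes with a trend or robust, other thresholds, 1 probe set per gene, and ordinary 2-sample statistics. Whether the replicate numbers of the titles pair the samples was checked from the correlation, across probe sets, of the difference between replicates 1 and 2 in the control arrays with that in the DHHC3-ablated arrays. It was 0.061, and the titles do not tie the numbers to a shared animal or day. The sample descriptions hold codes whose meaning is not given. The codes of replicate 2 in both groups share a number and those of replicate 1 do not, and their last letter is L in both control samples and R in both DHHC3-ablated samples. Whatever the letter stands for cannot be told apart from the group, and a shared animal for replicate 2 can neither be read from the labels nor ruled out.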

Results

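Gene expression was measured in orthotopic breast tumors to ask what changes in the tumor when the protein acyltransferase DHHC3 is depleted from the tumor cells. DHHC3, encoded by ZDHHC3, is an enzyme that attaches palmitate to cysteines of other proteins, and the study addresses tumor growth, oxidative stress and senescence. MDA-MB-231 cells with a control shRNA or with an shRNA against DHHC3 were injected into mammary fat pads, 10 injections each, and tumor volumes were followed over 30 days. The sample labels give the age of the tumors as 35 days. 2 tumors per group were hybridised, and the deposited table holds 137 probe sets that separate the groups. Median intensity over these probe sets was 312 and 351 arbitrary units on the control arrays and 484 and 458 on the DHHC3-ablated arrays.

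ZDHHC3 itself fell 3.62-fold in the DHHC3-ablated tumors. Its probe set, 218078_s_at, read 912 ± 82.9 (SD, n = 2) in control tumors and 252 ± 16.8 (SD, n = 2) in DHHC3-ablated tumors. The log2 fold change was -1.86 ± 0.11 (SE), with a limma adjusted p of 0.000193. Among the genes with 1 name, only TRBC1 had a larger fall. The level of the targeted transcript thus went with the labels on all 4 arrays, with 971 and 854 in the controls against 240 and 264 after ablation.

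In the DHHC3-ablated tumors, 101 of the 137 probe sets were higher and 36 were lower. Whether RNA quality or gene length went with this split was not analysed here. TXNIP, which encodes the thioredoxin-interacting protein that binds and inhibits thioredoxin, rose 2.57-fold, from 914 ± 11.9 to 2347 ± 41.6 (SD, n = 2 each). PRDX2, a peroxiredoxin that reduces hydrogen peroxide, rose 2.17-fold. GSTM3, a glutathione S-transferase, fell 2.03-fold, and S100A4, a calcium-binding protein linked to cell motility, fell 2.11-fold from the brightest level in the table, 9049 ± 427 (SD, n = 2). Among probe sets that rose, the median fold was 1.99 and the range was 1.57 to 4.11. Among those that fell, the median was 1.83 and the range was 1.64 to 4.25.

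TXNIP, COL6A3, ANKRD36B and RSRP1 were the brightest of the 12 genes with the largest rises. COL6A3, a chain of collagen VI, rose 3.14-fold, from 297 ± 46.0 to 927 ± 19.3 (SD, n = 2 each). ANKRD36B rose 2.98-fold and RSRP1, an arginine- and serine-rich protein, rose 2.41-fold. SMYD2, a lysine methyltransferase, rose 2.47-fold from 123 units. NAIP, a member of the inhibitor of apoptosis family that senses bacterial proteins, rose 2.60-fold from 69.3 units. The largest folds were at low intensity. VGLL3, a cofactor of TEAD transcription factors, rose 3.97-fold from 16.7 ± 8.08 to 62.6 ± 5.90 (SD, n = 2 each). KAZN, a desmosome-associated protein, rose 3.77-fold from 19.9 units, and PIP5K1B, a phosphatidylinositol phosphate kinase, rose 3.49-fold from 11.7 units. JAKMIP2 rose 2.94-fold from 41.8 units, GTF2I, a general transcription factor, rose 2.80-fold from 30.3 units, and SPDYE2 rose 3.22-fold from 75.5 units. The folds depended on the scaling, also those of the brighter genes. With each array centred on its median, which shifts every log2 fold change down alike, TXNIP was 1.80-fold, COL6A3 2.21-fold, ANKRD36B 2.09-fold and RSRP1 1.69-fold higher. After quantile normalization over the list, TXNIP was 2.19-fold, COL6A3 2.79-fold, ANKRD36B 2.51-fold and RSRP1 2.13-fold higher, nearer to the folds as deposited. The folds of the dim genes moved in other settings too. With a pseudocount of 16, VGLL3 was 2.43-fold, KAZN 2.49-fold and PIP5K1B 2.04-fold higher. After quantile normalization over the list PIP5K1B had a log2 fold change of 0. In each group it was the lowest probe set on 1 array and the second lowest on the other. This setting keeps only the ranks, so the 0 does not show an unchanged level. VGLL3 was then 1.86-fold higher without passing the test. KAZN was 1.40-fold, GTF2I 1.37-fold, NAIP 1.45-fold, JAKMIP2 1.54-fold, SMYD2 1.54-fold and SPDYE2 1.86-fold higher. SPDYE2, ANKRD36B, GTF2I and NAIP have close copies in the human genome, so which copy gave their signal is uncertain. The limma adjusted p of these 12 genes lay between 0.000193 for TXNIP and GTF2I and 0.00147 for VGLL3.

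The 12 lowest named genes included ZDHHC3, S100A4 and GSTM3. The largest fall was that of TRBC1, a constant segment of the T cell receptor beta chain, which went from 152 ± 7.76 to 37.9 ± 17.7 (SD, n = 2 each), or 4.25-fold; the hosts were athymic mice. BCL2A1, an anti-apoptotic member of the BCL2 family, fell 2.39-fold from 1151 ± 78.3 to 481 ± 3.60 (SD, n = 2 each), and STK17B, a kinase linked to apoptosis, fell 2.35-fold. ANAPC15, a subunit of the anaphase-promoting complex, fell 2.14-fold. PFDN4, a subunit of the prefoldin chaperone, fell 2.04-fold, from 1580 ± 3.70 to 776 ± 6.22 (SD, n = 2 each). DTNA, a dystrobrevin, fell 2.18-fold, and PHF14, a PHD finger protein, fell 2.05-fold. DHRS3, a retinaldehyde reductase, fell 2.03-fold from 145 units, and B9D1, a protein of the base of the cilium, fell 1.94-fold. After quantile normalization over the list the falls were larger: 8.36-fold for TRBC1, 4.60-fold for PHF14, 4.17-fold for DHRS3, 3.73-fold for STK17B, 3.44-fold for DTNA and 3.03-fold for B9D1. This setting keeps only the ranks, and TRBC1, PHF14 and DHRS3 were dim after ablation, so their larger folds do not show a stronger fall. With a pseudocount of 16, the log2 fold change of TRBC1 was -1.68, against -2.09 as deposited. Without DHHC3-ablated replicate 1 it was -1.59, and without DHHC3-ablated replicate 2 it was -2.58. The limma adjusted p of these 12 genes as deposited lay between 0.000193 for ZDHHC3 and 0.000953 for TRBC1.

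**Figure D1:**
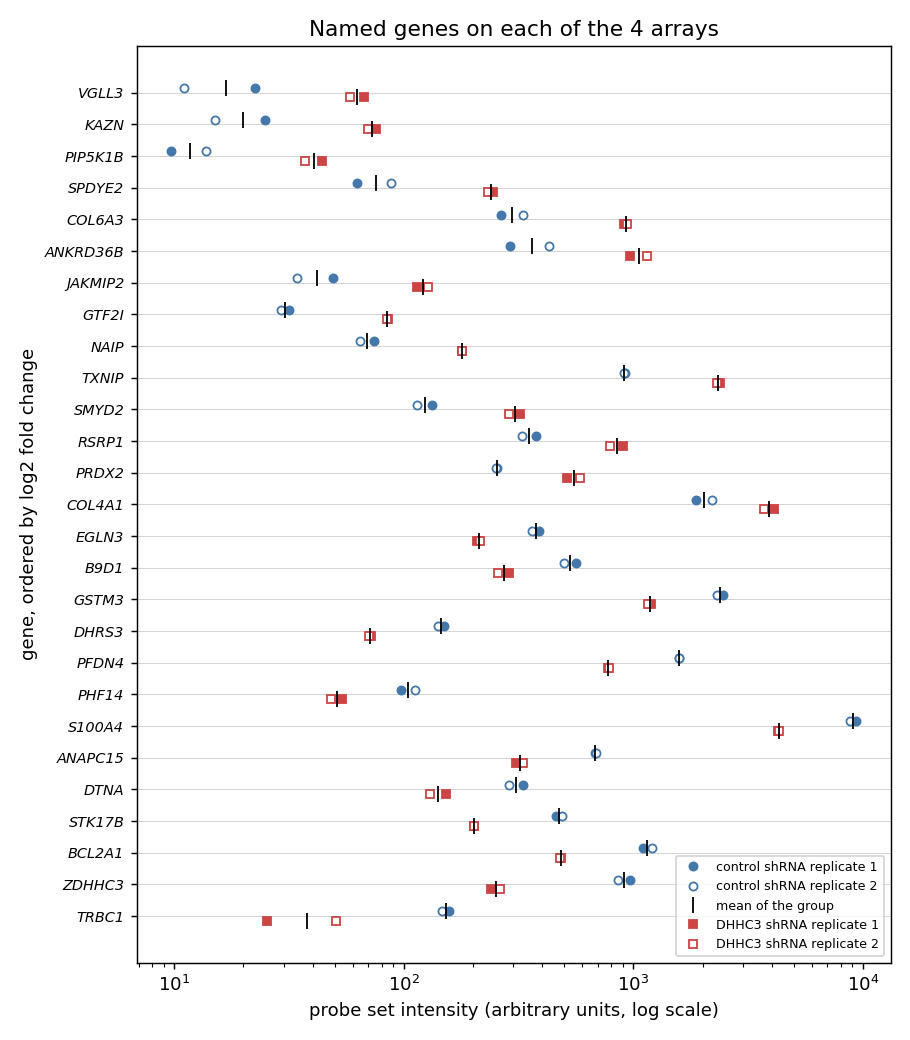
Intensity of each named gene's probe set (horizontal axis, arbitrary units, log scale) on the 2 control arrays (blue circles) and the 2 DHHC3-ablated arrays (red squares), with replicate 1 filled, replicate 2 open and each group's mean as a black bar. Genes are ordered by log2 fold change, and in every one the arrays of the 2 groups do not overlap; TXNIP moves from 914 to 2347 units and ZDHHC3 from 912 to 252.

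Of the 26 gene lists fixed beforehand, 6 had 1 member in the table and 20 had none. The thioredoxin list held TXNIP, and the antioxidant list held PRDX2, which read 255 and 252 units on the control arrays and 516 and 586 after ablation. The suffix of its probe set, 215067_x_at, marks probes that can bind other transcripts. PRDX2 was 1.52-fold higher with each array centred on its median and 1.54-fold higher after quantile normalization. The list of integrins, tetraspanins and matrix held COL4A1, a collagen of basement membranes, which rose 1.92-fold from 2031 ± 235 to 3898 ± 292 (SD, n = 2 each) but was 1.20-fold higher and did not pass after quantile normalization (limma adjusted p = 0.139). The list of hypoxia and glycolysis held EGLN3, a prolyl hydroxylase that acts on hypoxia-inducible factor, which fell 1.77-fold from 375 ± 17.5 to 212 ± 3.89 (SD, n = 2 each), or 2.69-fold after quantile normalization. The list of DHHC enzymes held ZDHHC3, and the fibroblast list held S100A4, which tumor cells express too. As deposited, all 6 passed over the 137 probe sets and adjusted over the list alone, as did every probe set in the table, so this does not set them apart. A single member does not describe its list.

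The lists of senescence and its secreted factors, proliferation, the unfolded protein response, the interferon response, inflammatory cytokines, apoptosis and p53 targets, and lipid and sterol metabolism had 0 members in the table. So had the lists of macrophage, neutrophil, NK cell, dendritic cell, B cell, endothelial, pericyte and smooth muscle, adipocyte, skeletal muscle, erythroid, mammary epithelium, keratinocyte and Schwann cell markers. Whether genes of these lists changed was not analysed here, since the table shows neither their levels nor whether they were tested.

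**Figure D2:**
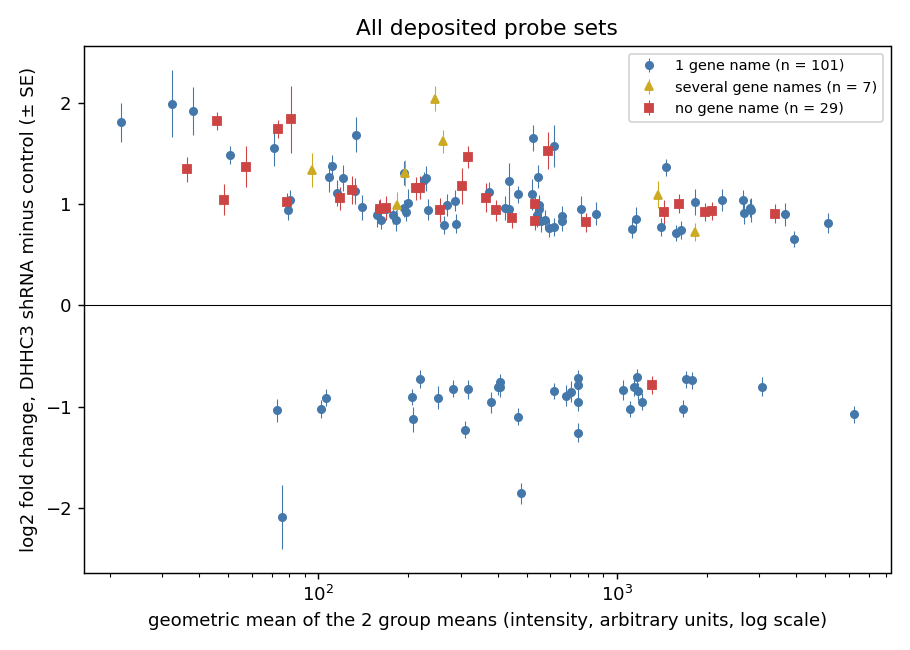
Log2 fold change between DHHC3-ablated and control tumors (vertical axis, ± SE of the limma fit, 2 arrays per group) against the geometric mean of the 2 group means (horizontal axis, intensity in arbitrary units, log scale) for the 137 probe sets, by whether the annotation gives 1 gene name (101), several (7) or none (29). No probe set lies near 0: the smallest rise is 1.57-fold and the smallest fall 1.64-fold.

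All 137 probe sets passed the limma test, with adjusted p from 0.000193 to 0.00218, and 60 of them differed at least 2-fold, 49 higher and 11 lower. The balance of 2-fold differences turned with the scaling: 13 were higher and 36 lower with each array centred on its median, and 6 higher and 32 lower after quantile normalization. Both settings by construction balance a list in which most members were higher, so this turn is no test of the direction. In all 137, both arrays of one group lay outside the range of the other, where chance gives 33.3% of probe sets. Within a group, the 2 arrays differed by a median of 0.15 on the log2 scale in the control tumors and 0.09 in the DHHC3-ablated tumors, against 0.96 to 1.00 between arrays of different groups. The list holds only probe sets that separate the groups, and the rule that chose them is not given. Neither the count nor the adjusted p-values are therefore independent evidence. An exact permutation test of 2 arrays against 2 cannot go below p = 0.333. After quantile normalization over the 137 probe sets, VGLL3, PIP5K1B and COL4A1 no longer passed, with limma adjusted p of 0.0594, 1 and 0.139. With ordinary 2-sample statistics in place of limma's moderated ones, TRBC1 and VGLL3, the largest named fall and rise, did not pass (adjusted p = 0.0532 and 0.0629 after Benjamini-Hochberg adjustment).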

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

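Of the 137 probe sets, the number past the limma threshold was 124 (88 higher, 36 lower) with each array centred on its median and 104 (68 higher, 36 lower) after quantile normalization, against 101 higher and 36 lower as deposited. These 2 settings moved the median log2 fold change over the list by -0.509 and -0.581, since by construction they balance a list in which most members are higher. After quantile normalization, 2 dim probe sets without a gene name changed sign, from log2 fold changes of 1.04 and 1.34 to -0.19 and -0.06, by more than the median shift. Neither passed there (limma adjusted p = 0.369 and 0.394). This setting keeps only the ranks within the list, so the changed sign does not show a fall in level. Ordinary 2-sample statistics with Benjamini-Hochberg adjustment passed 134. Asking also for a 2-fold difference left 60 (49 higher, 11 lower), and, in settings added after seeing the data, 49 (13 higher, 36 lower) with centring and 38 (6 higher, 32 lower) with quantile normalization. Without the dimmest 25% 102 of 102 passed, with 1 probe set per gene 99 of 99, with a threshold of 0.1 all 137, and in settings added after seeing the data 101 of 101 with 1 gene name and 109 of 109 without the _x_at suffix. Trend, robust and pseudocount settings, and leaving out each array in turn, kept all 137, with the lone array assumed to vary like the other group. ZDHHC3 stayed past the threshold throughout, with log2 fold changes from -1.95 to -1.76 when 1 array was left out, -2.37 after centring and -2.24 after quantile normalization. With the replicate number as a block (a pairing that neither the titles nor the correlation bears out) all 137 passed, and ZDHHC3 had an adjusted p of 0.003. Of 379 values of the other named genes under these alternatives, 374 kept direction and call. The list held only probe sets whose groups were already apart, so most settings could hardly do otherwise. The count is therefore not evidence of robustness. VGLL3, PIP5K1B and COL4A1 lost the call after quantile normalization, and VGLL3 and TRBC1 with ordinary 2-sample statistics. Quantile normalization moved the fold of 16 of the 27 named genes by over 1.5 times, with smaller rises and larger falls (KAZN from 3.77-fold to 1.40-fold, TRBC1 from 4.25-fold to 8.36-fold), and the pseudocount that of 3, VGLL3, KAZN and PIP5K1B. The groups did not overlap in 128 probe sets after quantile normalization. A random block on the number in the sample descriptions, added after seeing the data, gave no estimate of the correlation. Set tests (camera, fry) were not run, as no list had 5 members. Signal over background is unknown: the table has no detection calls, and the dimmest values, such as the 9.69 units of PIP5K1B on 1 control array, have folds that background would change.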

Other observations

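The tests of unnamed probe sets in this part were chosen after the results were seen, and the genes in this paragraph and the next were picked after their values were seen. Among genes that the report does not name, the aldo-keto reductase AKR1C1 fell 1.75-fold (531 to 304 units) and the glutathione transferase GSTZ1 fell 1.73-fold (972 to 563 units), in the direction of GSTM3. CDKN3, a phosphatase that acts on cyclin-dependent kinases, fell 1.74-fold from 4053 units, and CENPN, a centromere protein, fell 1.67-fold from 2319 units. LIPA, the lysosomal acid lipase, fell 1.66-fold from 2203 units. RPS21, a protein of the small ribosomal subunit, fell 1.93-fold, and ATP5MJ, a subunit of mitochondrial ATP synthase, fell 1.80-fold, while MRPL57, a mitochondrial ribosomal protein, rose 1.94-fold. The leukocyte phosphatase PTPN7 fell 1.87-fold (282 to 151 units), the phosphodiesterase PDE4B 1.88-fold (344 to 183 units) and HCLS1, a hematopoietic signalling protein, 1.66-fold (283 to 171 units). BNIP1 and GEMIN2 each had 2 probe sets, which gave falls of 1.69-fold and 1.75-fold for BNIP1 and of 1.65-fold and 1.74-fold for GEMIN2. The probe sets of AKR1C1 and MRPL57 and both of GEMIN2 have the suffix _x_at, so they can bind other transcripts. After quantile normalization over the list the falls were 2.67-fold for AKR1C1, 2.95-fold for PTPN7, 2.96-fold for PDE4B and 2.63-fold for 1 of the 2 BNIP1 probe sets.

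Among the rises as deposited, ATM, a kinase of the DNA damage response, was 1.71-fold higher (470 to 803 units). RAD1, of a DNA damage checkpoint clamp, was 1.75-fold higher and XRCC2, of homologous recombination, 1.94-fold higher, both on probe sets with the suffix _x_at. PRKAA1, a catalytic subunit of AMP-activated kinase, rose 1.73-fold from 201 units. A further collagen, COL13A1, rose 1.64-fold on an _x_at probe set, in the direction of COL6A3 and COL4A1. ZFP36L2, an RNA-binding protein that promotes mRNA decay, rose 1.94-fold (2007 to 3899 units), and TRIO, a guanine nucleotide exchange factor, rose 2.05-fold (1850 to 3799 units). These rises depended on the scaling. With each array centred on its median, ATM was 1.20-fold, PRKAA1 1.22-fold, RAD1 1.23-fold and COL13A1 1.15-fold higher and none of these 4 passed (limma adjusted p = 0.0957, 0.07, 0.0559 and 0.186), while XRCC2, ZFP36L2 and TRIO did. After quantile normalization all 7 passed, with ATM 1.37-fold, PRKAA1 1.23-fold, RAD1 1.76-fold, COL13A1 1.42-fold, XRCC2 1.13-fold, ZFP36L2 1.26-fold and TRIO 1.30-fold higher. The largest rise in the table, 4.11-fold, was on a probe set with several gene names.

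Probe sets for which the annotation lists no gene rose more often than named ones: 28 of 29 were higher, against 73 of 108 with 1 or more names (Fisher's exact test, two-sided p = 0.000789). The tests in this paragraph take probe sets as independent, though all were read on the same 4 arrays. Their p-values therefore do not measure the spread between tumors. Cross-hybridisation marked by the _x_at suffix is argued against as the whole cause, since without those probe sets 18 of 18 unnamed ones rose against 61 of 91 named ones (Fisher's exact p = 0.00276). A constant background added to the ablated arrays would give like gains, but the gains of the 28 ranged from 34.8 to 2150 units, a ratio of 62. Background alone could thus not give all 28 gains. Every listed probe set, however, separated the nearest arrays by at least 1.56-fold, so bright ones in the list had to gain more units. Whether background raised the dim ones is therefore not decided by this range. Dim probe sets rose more often, yet with names permuted within 3 bins of mean level the excess remained (22.2 expected, 28 seen, permutation test, two-sided p = 0.0043). Of the unnamed rises, 13 lay in the dimmest bin, 9 in the middle and 6 in the brightest. Differences of level within a bin were not removed, so a part played by level stays open. A change in poorly annotated or intronic transcripts with DHHC3 ablation, a difference in RNA quality between the tumors, a dependence on transcript length, and the unknown filter all stay open, since probe positions, RNA quality, gene lengths and the rest of the array were not analysed here.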
